A study of Caenorhabditis elegans with 6 samples.

How the data were processed

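Total RNA from whole mixed-stage embryos of the nematode Caenorhabditis elegans was measured on 6 Affymetrix arrays, 3 of the mir-35-41(nDf50) deletion mutant and 3 of the wild type strain N2. Per the labels' protocols, cultures were grown at 20 degrees Celsius on nematode growth medium with egg yolk, embryos were taken from mixed cultures with hypochlorite, RNA was extracted with Trizol, and biotin-labelled antisense RNA was made with a single-round amplification kit. The mutant strain is given as VT2935 without nEx1187, by nomenclature an extrachromosomal array. The source and stage labels say mixed-stage embryos, and the titles say embryo without a stage. A free-text line of each sample names a narrower early stage instead, an earlier one for mutant replicates 1 and 2 than for the other 4 samples, in words that do not belong to nematode development, and it was not used. Each array was assigned to its group and replicate by the column name given in its description and by its title. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be in part technical.

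The deposited gene-annotated table holds a normalized intensity per probe set and array on a linear scale. The submitters' processing notes name Affymetrix Expression Console. Its version and the background correction, normalization and summary method are not given in the sources used here. The series value table holds the same deposited values as log2, and log2 of the linear table differed from it by at most 5.63e-06. Because the normalization is the authors', a change shared by most genes would be removed before these tables, and every difference below is relative to the other genes on the array. For arrays it can be said only that their number, 3 per group, limits the precision.

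The log2 of the linear intensity was used with no added constant. Of 22625 probe sets, 77 array controls were left out and 22548 features were tested with no filter on dim features. A single gene was named by 20865 of them, several genes by 687 and none by 996. Names in the table were updated through a RefSeq gene table of assembly WBcel235, which was used for names, chromosomes, gene order and the genomic length of genes. It matched 16045 features by symbol and 3566 by sequence name, and 1254 kept the name in the file. The features name 17137 different genes. No column of per-sample values was left without a sample.

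The comparison was fixed before the data were examined, as were the gene lists, the rule for named genes and the alternatives, except those said below to have been added. Mutant and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block or covariate), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Differences are log2 mutant minus log2 wild type, with the standard error of the moderated fit. The groups share replicate numbers, and nothing in the labels pairs the arrays, so the fit with the number as a block was an alternative. For gene lists, a gene was represented by its single-gene feature with the highest mean over all 6 arrays. The 37 lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 37 lists. The alternatives were camera with an estimated correlation and fry, which tests whether the genes of a list move, without comparing them with other genes. Members were also counted with adjustment over the list alone. X-linked genes were compared with autosomal genes by camera and by 100000 random draws of genes.

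The text names the 10 largest rises and 10 largest falls among features that name 1 gene, passed the threshold and had all 3 mutant arrays on 1 side of all 3 wild type arrays. If fewer passed in a direction, all were named. It also names up to 4 members with the smallest p of each list described, and always sup-26, nhl-2, egl-1, her-1, tra-1, tra-2, fem-1, fem-3, xol-1, sdc-2 and any feature of the deleted locus. Other genes are named only as chosen after their values were seen.

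Alternatives covered each array left out in turn, the replicate block, the series value table, quantile normalization again, centring on the array median, removal of features below the median mean level, addition of 16 before log2, an intensity trend with a robust prior, array weights, a minimum of 2-fold and 1 feature per gene. Gene ontology terms with 10 to 300 genes from the table's own annotation, leaving out wild type replicates 1 and 3 together, averaging mutant replicates 2 and 3 as 1 sample, and gene-by-gene array weights were added after seeing the data. The fit was tested on simulated data with the real feature means and spreads over 22548 features, 200 of them changed. At 3 arrays against 3 it recovered 0 of 200 features changed by 2-fold with 0 false calls, 162 of 200 changed by 4-fold with 5 false calls, and 193 of 200 changed by 8-fold with 10 false calls. The simulated arrays were independent, with 1 spread per feature for both groups. No simulated arrays were nearly alike or stood apart, as real ones did, so these false calls are not an error rate of the real fit. The list test, run on 17137 simulated genes, found the 1 moved list of 40 genes and 0 of the unmoved lists. These genes were drawn independently of each other. The simulation therefore cannot show how often the preset correlation gives false calls for lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.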

Results

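The mir-35 family is a set of embryonic microRNAs that share a seed sequence and are together needed for embryonic development, and it has been linked to the choice between hermaphrodite and male fates. The nDf50 deletion removes the members from mir-35 to mir-41. The arrays address which embryonic mRNAs differ when these microRNAs are missing, at 20 degrees Celsius. There were 3 mutant and 3 wild type arrays. The median log2 intensity was between 6.49 and 6.56 on the mutant arrays and was 6.43, 6.51 and 6.29 on wild type replicates 1, 2 and 3. No feature names a microRNA of the deleted locus or a gene of its Y62F5A host clone (0 features), so the deletion itself could not be read on these arrays.

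The genes that differed between the genotypes were nearly all higher in the mutant. The largest rise was srlf-34, at 10.29 ± 0.05 in the mutant and 7.02 ± 0.30 in wild type (mean log2 intensity ± SD, n = 3 arrays each), 9.64-fold higher with a limma adjusted p of 0.00557. The 2 features of C53B7.3 rose by 3.11 ± 0.38 and 2.85 ± 0.29 (log2 difference ± SE), and K09D9.1 rose by 2.73 ± 0.20. Among genes with a known role, the transthyretin-related gene ttr-21 rose by 2.61 ± 0.23, kreg-1, named for its regulation by the stress kinase KGB-1, rose by 2.44 ± 0.30, and lon-1, a secreted regulator of body size acting with TGF-beta signalling, rose by 2.40 ± 0.25. W01F3.2, F16B4.4 and C25H3.10 rose by 2.38, 2.37 and 2.32 on the log2 scale. The single fall was F43G6.8, which fell 5.93-fold from 8.89 ± 0.63 to 6.32 ± 0.21. It and srlf-34 lie on chromosome II, 62 and 267 protein-coding genes from the deleted locus.

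**Figure D1:**
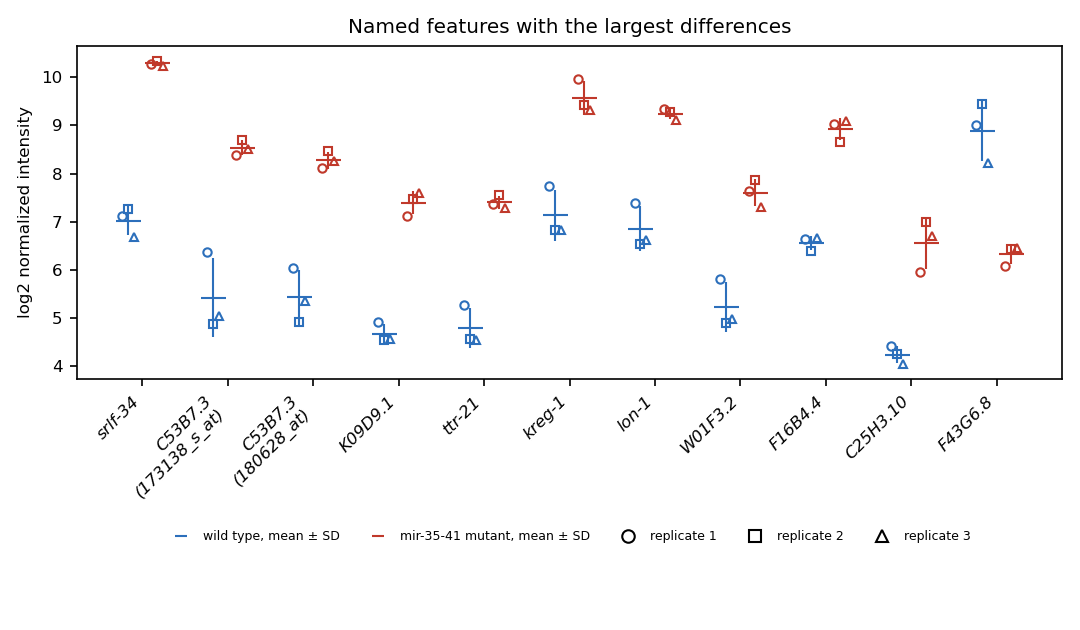
Log2 normalized intensity of the 11 named features with the largest differences past the threshold, on each of the 6 arrays. Open symbols are single arrays, bars show the mean and SD of 3 arrays, and on every feature the 3 mutant arrays lie on 1 side of the 3 wild type arrays. Only F43G6.8 is lower in the mutant, at a mean of 6.32 against 8.89.

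In all, 29 of 22548 features passed the threshold, 28 higher and 1 lower, and the 28 of them that name a single gene name 27 genes. The further genes of this paragraph were named after their values were seen. They include fipr-2, of a fungus-induced peptide family (4.92-fold), the antimicrobial peptide genes nlp-29 (4.84-fold) and nlp-30 (2.83-fold), the cathepsin B-like protease cpr-4 (3.78-fold), the metalloprotease zmp-4 (3.76-fold) and aakg-4, a gamma subunit of AMP-activated kinase (3.00-fold), each with an SE between 0.18 and 0.28 on the log2 scale. A feature shared by the metal-responsive genes numr-1 and numr-2, which it cannot tell apart, rose 6.27-fold. The smallest rise was 2.62-fold, for F13A7.11. All 29 features differed at least 2-fold and had no overlap between the groups. Over all features 3501, or 15.5%, had no overlap, 1389 higher and 2112 lower. Chance gives 10% only if the 6 arrays are independent, and more if arrays of a group are alike. Mutant replicates 2 and 3 were nearly alike (r = 0.998), so the 15.5% is not to be read as an excess.

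The number of calls depends on single arrays: leaving out mutant replicate 1, 2 or 3 left 0 calls by limma, with 2203, 1151 and 1008 features at an unadjusted p under 0.05, while leaving out wild type replicate 1, 2 or 3 gave 47, 1289 and 1. In each of these fits all 29 features differed at least 2-fold. This was fixed in advance, because on each of them every mutant array lay at least 2-fold from every wild type array.

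Genes of the sex determination pathway and reported targets of the family showed no difference past the threshold. In the simulation the fit recovered 0 of 200 features changed by 2-fold. Differences of about that size or less can therefore be missed, and the lack of calls does not show that these genes are unaffected. The male-promoting signal her-1, which blocks the receptor TRA-2, was at 9.04 ± 0.37 in the mutant and 8.28 ± 0.33 in wild type (mean log2 intensity ± SD, n = 3 each), a difference of 0.76 ± 0.25 (SE) with an adjusted p of 0.427, and all 3 mutant arrays were above all 3 wild type arrays. The switch gene xol-1 differed by 0.71 ± 0.29 and 0.20 ± 0.26 on its 2 features (adjusted p = 0.480 and 0.714). The differences of sdc-2, which represses her-1, on its 2 features corresponded to 2.29-fold and 2.14-fold, with SEs of 0.60 and 0.58 on the log2 scale and wild type SDs of 1.27 and 1.15 (adjusted p = 0.524 and 0.542). Further down the pathway fem-3 differed by 0.64 ± 0.35, fem-1 by 0.27 ± 0.20 and 0.36 ± 0.30, tra-2 by 0.33 ± 0.24 and -0.04 ± 0.16, and the 4 features of tra-1 by between -0.47 and 0.09. The microRNA cofactor gene nhl-2 differed by 0.26 ± 0.21 (adjusted p = 0.621) and the cell death activator egl-1 by -0.29 ± 0.36 (adjusted p = 0.716). sup-26, which encodes an RNA-binding repressor of tra-2, has 0 features that name it.

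As lists, the 21 measured sex determination genes had a median log2 difference of 0.05 (camera adjusted p = 0.219), and the 4 measured reported targets had one of 0.10 (adjusted p = 0.443), against -0.10 for all genes. In both lists 0 members passed over all genes or adjusted over the list alone. Members with the smallest p included ceh-39 (-0.56) and mog-1 (0.94) in the first list and lin-23 (0.35) in the second.

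Innate immunity genes were higher as a group by camera, with a median of 0.22 and an adjusted p of 1.08e-06 (adjusted p = 0.761 with an estimated correlation). Of 46 measured members 29 had a positive difference, 2 rose past the threshold over all genes (nlp-29 and nlp-30) and 10 adjusted over the list alone, with 0 lower in either count. Besides these, the cysteine protease gene cpr-3 was 2.15-fold higher and the caenacin peptide gene cnc-4 5.70-fold higher, with adjusted p of 0.00273 and 0.00309 over the list alone and 0.0729 and 0.0888 over all genes. Over the 16 alternatives the adjusted p ranged from 3.86e-09 to 0.761. By fry, members moved in either direction with an adjusted p of 0.00796, and in 1 direction with 0.162.

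With the preset correlation 15 of the 37 lists passed, 7 higher and 8 lower, and with an estimated correlation 0 passed, the other 14 of the 15 each having an adjusted p of 0.954. All-gene differences had a median of -0.10, and centring the arrays moved it to -0.23, a shift of -0.13, so list medians are to be read relative to that of all genes. Wild type replicate 3 stood apart from the other arrays, and 5 of the 15 lists passed without it. These were innate immunity, proteasome, neuropeptides, the F-box B family and maternal genes. Without wild type replicate 2 the proteasome, neuropeptide and intestinal lists had adjusted p of 0.239, 0.336 and 0.239. After quantile normalization again 10 lists passed, 8 of them among the 15, and dosage compensation, intestine, histones, oxidative phosphorylation, ribosomal proteins, chemoreceptors and lectins did not.

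Besides immunity, 3 lists with called members or leading genes of known function were higher (adjusted p = 0.954 for each with an estimated correlation). The 31 measured proteasome genes had a median of 0.23 (adjusted p = 0.000843), with pas-2 at 0.85 ± 0.20 and pas-7 at 1.00 ± 0.26. The median deviation of this list from its gene means was 0.45, 0.04 and -0.03 on mutant replicates 1, 2 and 3 and -0.33, -0.39 and 0.33 on wild type replicates 1, 2 and 3. Neuropeptide genes of the nlp and flp families, 86 in number, had a median of 0.17 (adjusted p = 0.000315), and 2 rose over all genes, again nlp-29 and nlp-30. Adjusted over the list alone 5 were higher and 1 lower, the latter nlp-10 at -2.18 ± 0.40. The median deviation of the neuropeptide list was 0.03, 0.06 and 0.10 on mutant replicates 1, 2 and 3. On wild type replicates 1, 2 and 3 it was 0.11, -0.28 and -0.01. Wild type replicate 1 thus lay above every mutant array, and the rise rests mainly on wild type replicate 2. Intestinal genes had a median of 0.01 in 46 members (adjusted p = 0.0268), with cpr-4 past the threshold over all genes. Adjusted over the list alone 4 were higher, cpr-4, the glutathione transferase gene gsto-1 (1.18), the metallothionein gene mtl-1 (1.53) and the ferritin gene ftn-1 (1.28), and 1 was lower.

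Small RNA pathway genes (55, median 0.20, adjusted p = 0.00127), UDP-glucuronosyltransferases (62, median 0.11, adjusted p = 0.00423) and the dosage compensation complex (10, median 0.40, adjusted p = 0.0209) were also higher, with 0 members past the threshold over all genes or adjusted over the list alone (adjusted p = 0.954 for each with an estimated correlation). Their leading members were mut-2 (2.14-fold, SE 0.29 on the log2 scale), nrde-2 (1.21 ± 0.41), drh-3 (1.67 ± 0.57) and sid-1 (0.42 ± 0.15), then ugt-64 (0.91 ± 0.21), and dpy-26 (1.16 ± 0.45) and mix-1 (0.86 ± 0.39). The dosage compensation genes had median deviations of -0.36 and -0.71 on wild type replicates 1 and 3 and of 0.46 on wild type replicate 2, so the wild type arrays did not agree among themselves. The small RNA genes had 0.0018, 0.06 and -0.35 on wild type replicates 1, 2 and 3. On wild type replicates 1 and 3, drh-3, nrde-2 and dpy-26 were lower than on all other arrays by 2.19, 1.47 and 1.44 log2 units. Wild type replicate 2 was near the mutant arrays on these genes, so their rises rest on the other 2 wild type arrays.

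**Figure D2:**
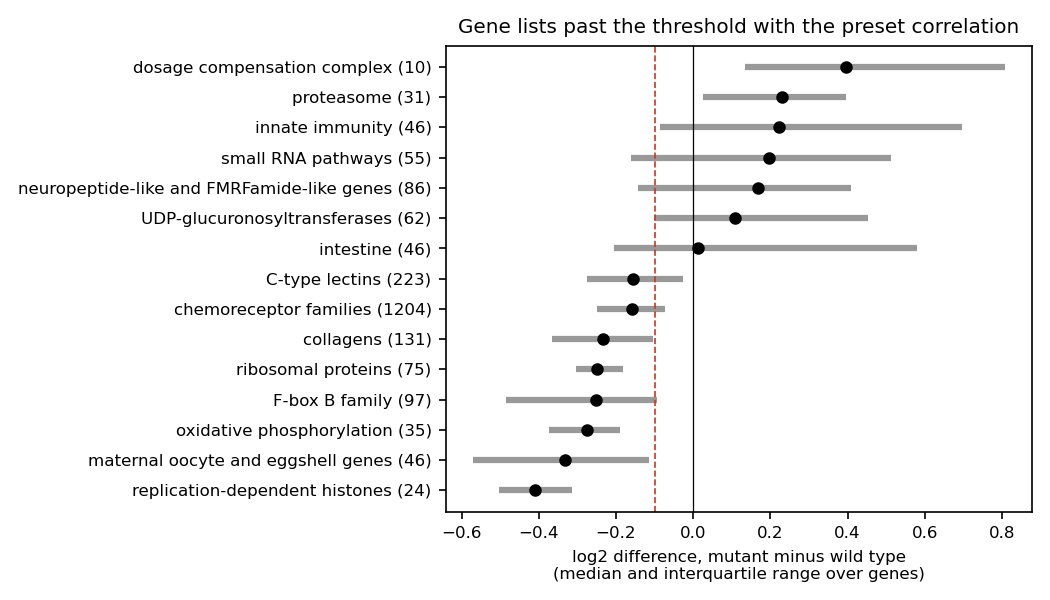
Median log2 difference, mutant minus wild type, of the 15 gene lists past the threshold with the preset correlation. Points are medians over genes, grey bars span the interquartile range, numbers in brackets count measured genes, and the dashed line marks the median of all genes at -0.10. The medians run from -0.41 for histones to 0.40 for the dosage compensation complex, and 0 of these lists passed with an estimated correlation. After quantile normalization again the ribosomal list changed direction.

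Maternal oocyte and eggshell genes were lower as a group, with a median of -0.33 in 46 members and an adjusted p of 0.000766 (adjusted p = 0.954 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The eggshell proteoglycan genes cpg-2 (-1.14 ± 0.24) and cpg-3 (-0.86 ± 0.23), the meiotic spindle gene mei-1 (-0.61 ± 0.16) and the RNA-binding protein gene puf-3 (-0.87 ± 0.26) had the smallest p. The median deviation of this list was 0.22 and 0.40 on wild type replicates 1 and 3 and -0.14 on wild type replicate 2, which lay near the mutant values of -0.17 to -0.24.

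Replication-dependent histones (24 genes, median -0.41, adjusted p = 0.00628), ribosomal proteins (75, median -0.25, adjusted p = 0.00150) and oxidative phosphorylation genes (35, median -0.27, adjusted p = 0.00415) were lower with 0 members past either count (adjusted p = 0.954 for each with an estimated correlation). In these 3 lists the median deviation of wild type replicate 3 was 1.03, 0.64 and 0.61 and that of every other array was negative, and without that array the adjusted p was 0.702, 0.245 and 0.933, with histone and ribosomal medians of 0.05 and 0.02. After quantile normalization again the ribosomal proteins had an adjusted p of 0.603 and the opposite direction against other genes. The genes with the smallest p were his-41 (-0.52), rpl-24.2 (0.41) and nuo-1 (-0.38).

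Collagens (131, median -0.23, adjusted p = 0.00133), the F-box B family (97, median -0.25, adjusted p = 9.34e-05), chemoreceptor families (1204, median -0.16, adjusted p = 9.34e-05) and C-type lectins (223, median -0.16, adjusted p = 0.0366) were lower (adjusted p = 0.954 for each with an estimated correlation). Among their members, 0 collagens and 0 F-box B genes passed either count, although fbxb-65 was at -0.99 ± 0.24 and col-131 at -0.89 ± 0.17. At an unadjusted limma p under 0.05, 5 collagens were higher and 9 lower. The chemoreceptor list, drawn by symbol pattern, also takes in srlf genes and the kinase genes src-1 and src-2, and it holds srlf-34, its only member past the threshold, and its direction and that of the lectins turned when dim features were removed. Of the lectins clec-5 (1.18 ± 0.17) was higher adjusted over the list alone. Wild type replicate 3 had median deviations of 0.29 for chemoreceptors and for lectins and 0.41 for collagens. For collagens wild type replicate 2, at -0.23, lay below all mutant arrays (-0.15 to -0.06). The F-box B family had median deviations of 0.06, -0.23 and -0.27 on mutant replicates 1, 2 and 3. On wild type replicates 1, 2 and 3 they were 0.19, 0.10 and 0.14. Mutant replicate 1 thus lay nearer the wild type arrays, and the fall rests mainly on mutant replicates 2 and 3, which were nearly alike.

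The other lists did not pass. Markers of tissues formed late in embryogenesis had medians of -0.12 for epidermis and cuticle (57 genes, adjusted p = 0.604), 0.03 for body wall muscle (46, 0.923), 0.05 for pharynx (25, 0.219) and -0.0046 for neurons (68, 0.443). Adjusted over the list alone, 3 epidermal genes were higher, the cuticle collagen genes dpy-9 (1.63 ± 0.24), sqt-2 (1.33 ± 0.21) and dpy-8 (1.35 ± 0.28). Early zygotic genes had a median of -0.05 (adjusted p = 0.923). Of material from adults or males, sperm genes had a median of -0.18 (adjusted p = 0.193), major sperm proteins -0.13 (0.822), vitellogenins and adult body markers -0.30 (0.313) and male soma markers -0.13 (0.882), and lys-4 (1.31 ± 0.18) was higher adjusted over the list alone. Cell cycle genes (-0.06, adjusted p = 0.796), synMuv B and chromatin repressors (0.10, 0.167), germ granule and germline genes (-0.06, 0.909), apoptosis genes (-0.03, 0.511) and stress response genes (-0.07, 0.828) had 0 members past either count.

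Among the remaining families, F-box A genes had a median of -0.04 (adjusted p = 0.411) with 3 higher over the list alone, led by fbxa-150 (1.06). Hedgehog-related genes had a median of -0.17 (0.314) with grl-21 (6.39-fold) and grl-4 higher over the list alone, and glutathione S-transferases one of -0.05 (0.662) with gst-22 (1.15) higher. Cytochromes P450 (-0.06, adjusted p = 0.694), nuclear hormone receptors (-0.06, 0.822) and MATH and BATH genes (-0.09, 0.443) had 0 members past either count. For F-box A genes, glutathione S-transferases, cytochromes P450, nuclear hormone receptors, cell cycle, apoptosis, neuronal and early zygotic genes the median was negative while the mean was positive.

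X-linked genes were compared with autosomal genes because sex determination in this animal acts with dosage compensation of the X. The median difference was -0.06 over 2270 X-linked genes and -0.10 over 14022 autosomal genes, 0.04 apart. Random draws of genes gave a permutation p of 1e-05, the smallest that 100000 draws can give, but this p treats genes as independent. Across arrays camera gave p = 0.311, and p = 0.493 with an estimated correlation.

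Genotype was not the main axis along which the arrays differed. The first principal component held 58.5% of the variance, with wild type replicate 3 at 78.6, wild type replicate 1 at 28.5, wild type replicate 2 at -22.7 and the mutant arrays between -36.8 and -14.7. Wild type replicate 2 correlated with the mutant arrays at 0.984 to 0.987 and with wild type replicates 1 and 3 at 0.976 and 0.950. Mutant replicates 2 and 3 were closest, at 0.998, and 12 features differed at least 2-fold between them, against 579 to 624 between mutant replicate 1 and either. They were kept as 2 samples, as labelled. Some genes differed widely between them, such as acdh-1 at 8.44 and 5.35, chosen after its values were seen, but this does not show that they are independent. Counted as 1 sample, they left 0 features past the threshold by limma. Wild type replicate 3 held 13773 distinct values, and the other arrays held 19141 to 20241.

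**Figure D3:**
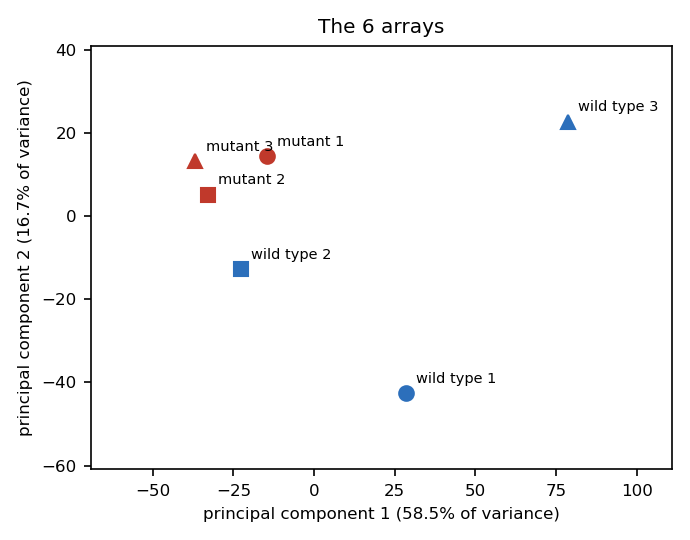
The 6 arrays on the first 2 principal components of log2 intensity over 22548 features, with 58.5% and 16.7% of the variance. Red symbols are mutant and blue symbols wild type arrays, numbered by replicate. Wild type replicate 2 lies at -22.7 on the first component, near the mutant arrays, and wild type replicate 3 at 78.6.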

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

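Leaving out both wild type replicates 1 and 3, counting mutant replicates 2 and 3 as 1 sample and gene-by-gene array weights were tried only after the results had been seen. All 29 called features kept their sign after quantile normalization again. Centring could not turn a sign, since it moves every difference by the same -0.13 and the smallest called difference was 1.39. Fits that leave out, weight or average arrays could not turn it either, since the groups do not overlap on these features. What varied was how many passed. Each array left out in turn gave 0 to 1289 features past the threshold, 0 to 1096 higher and 0 to 193 lower, with fewer arrays in each fit. By limma, leaving out wild type replicates 1 and 3 together left 0, and counting mutant replicates 2 and 3 as 1 sample left 0, with 2204 and 1059 features at an unadjusted p under 0.05. A sample left alone in its group is assumed to vary like the others. Quantile normalization again gave 3 features, all 3 higher and 0 lower, and centring on the array median gave 50, 47 higher and 3 lower. Adding 16 before log2 gave 8, all 8 higher and 0 lower, and an intensity trend with a robust prior gave 46, 45 higher. Array weights gave 13639, 4968 higher and 8671 lower, from a weight estimate that did not converge and set wild type replicate 1 at 21.1 and wild type replicate 3 at 0.0955. Gene-by-gene weights gave 3608, 2016 higher and 1592 lower. Except for the replicate block below, the other planned settings stayed within 1.5 times of the main count. Apart from the fits with fewer arrays, the cause was not tested.

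With the replicate block 19 features passed, 18 of them higher, and 16 were among the 29. The deviations of same-numbered arrays correlated at -0.03, 0.07 and -0.18, so the numbers do not pair the arrays.

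Of 37 lists 15 passed in the main test, 0 with an estimated correlation, 0 by directional fry, 2 by fry for either direction, 8 without dim features, 10 after quantile normalization again (8 shared with the main test), and 5 to 19 with each array left out. Directions turned for ribosomal proteins after quantile normalization (median -0.020) and without wild type replicate 3 (0.016), for histones without that array (0.045), and for C-type lectins (0.12) and chemoreceptors (0.056) without dim features. With each array left out the ribosomal median ran from -0.41 to 0.016 and the histone median from -0.65 to 0.045. A feature of fem-1 was called at -0.27 with array weights, against 0.36 in the main fit. The cause was not tested. The difference of X-linked and autosomal medians stayed between 0.01 and 0.06 with each array left out, and camera called it in 0 settings. The planned test of seed matches in 3' untranslated regions was not run, because no genome was used here.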

Other observations

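The tests of the 2 peptide and transthyretin-related families, of other array splits, of the deleted locus, of older embryos, of gene lists within a set of features, of swapped labels, of the gap that parts the labelled groups and of RNA degradation were chosen after the results they bear on had been seen, except that for transthyretin-related genes, gene span, the intensity trend and the position of wild type replicate 2 in fits without it the expected outcome was written before the value was computed.

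Other members of the secreted peptide families of called genes were looked at. Of 30 measured genes of the cnc, fip and fipr families and the nlp-29 cluster, 3 were called (fipr-2, nlp-29 and nlp-30). Among the 27 left, 11 were higher and 0 lower at an unadjusted p under 0.05, including cnc-4 (2.51 ± 0.39, log2 difference ± SE), fipr-26 (1.37 ± 0.33) and cnc-8 (1.02 ± 0.21), with a median of 0.22. Against all other uncalled genes camera gave p = 2.17e-06, and p = 0.0403 with an estimated correlation. With each array left out the latter ranged from 0.0431 to 0.0864 and stayed under 0.05 in 2 of 6 fits. These families were put together after high members had been seen, so the test leaves open whether they are higher as a class.

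Transthyretin-related genes were looked at in the same way. Besides the called ttr-21, 40 were measured, of which 13 were higher and 0 lower at an unadjusted p under 0.05. Among these were ttr-15, at 11.70 in the mutant against 8.65 in wild type, and ttr-18, at 9.43 against 7.76, and ttr-26 differed by 2.69 ± 0.35. Camera gave p = 2.58e-07, and p = 0.0347 with an estimated correlation, which ranged from 0.0224 to 0.110 with each array left out and stayed under 0.05 in 2 of 6 fits. Both families were found and tested on the same arrays, so that they may be higher as a class is a hypothesis, and these 2 p-values are not adjusted. Of metal and stress genes looked at beside kreg-1 and the numr features, mtl-1 differed by 1.53 and the 10 features of mtl-2, cdr-1, hmt-1, gst-4, hsp-16.2, hsp-4 and hsp-6 by between -0.63 and 0.32, with 0 past the threshold.

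Gene ontology terms, tested after seeing the data, gave 6 of 250 terms higher and 2 lower with the preset correlation and 0 with an estimated one (adjusted p = 0.960 each). DNA repair (72 genes, median 0.24, adjusted p = 0.00223) and defense response to fungus (12 genes, median 0.38, adjusted p = 0.00262) led the higher terms. Of the 72 DNA repair genes 12, among them mre-11, rad-50 and exo-1, are low on wild type replicates 1 and 3 alone, and the median deviation of the term was -0.11 and -0.43 on these arrays and 0.06 on wild type replicate 2. The lower terms were nucleosome assembly (48 genes, median -0.38) and chemical sensory perception (234 genes, median -0.15), with median deviations of 0.81 and 0.25 on wild type replicate 3. Of the 28 called features with a known chromosome 14 were on chromosome V, which carries 4559 of the 19611 such features tested (Fisher's exact p = 0.00241, across features that are not independent). This test was not planned, and its p is not adjusted for the choice of the chromosome with the most calls.

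The 29 calls were weighed first. Of the 10 splits of the 6 arrays, 1 gave as many calls, the real one, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. Cis effects of variants that travelled with the deletion on chromosome II cannot account for the 24 called features on other chromosomes, while for 2 of the 4 on chromosome II, F43G6.8 and srlf-34, which lie 62 and 267 protein-coding genes from the locus, this cannot be told apart from an effect of the microRNAs because strain and deletion go together. A larger share of older embryos cannot be told apart either. Epidermal, muscle, pharyngeal, neuronal and intestinal markers had a highest upper quartile of 0.58. They are already expressed in mixed stages and would hide a small share. The cuticle genes dpy-9 (1.63), sqt-2 (1.33) and dpy-8 (1.35) were higher over their list alone. The median of that list, -0.12, was near the -0.10 of all genes, and that of collagens was -0.23. Maternal oocyte and eggshell genes, which older embryos would lower, had a median of -0.33. Their camera adjusted p was 0.000766, and 0.954 with an estimated correlation, and wild type replicate 2 lay near the mutant arrays. Loss of the microRNAs and background variants elsewhere in the strain stay open.

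A second pattern was a set of 407 features at least 1 log2 unit lower on wild type replicates 1 and 3 than on all 4 other arrays, where the next pair of arrays had 27. It holds a feature of lin-35, the retinoblastoma homologue (5.06 and 4.56 against 7.59 to 7.82), and 0 of the 37 lists were over-represented in it (lowest Fisher adjusted p = 0.497). Such features enter the main comparison as spread within the wild type, and they also lower the wild type mean. Best correlations could not decide on a swap between the groups. Of the mutant arrays 0 correlated best with wild type replicate 1 or 3, but mutant replicates 2 and 3, nearly alike at 0.998, had each other. Wild type replicate 1 itself correlated best with wild type replicate 2 (0.976), and that array with mutant replicate 3 (0.987). Best partners thus did not follow the groups. Degraded RNA would need raised 3'/5' ratios of the control genes on both wild type replicates 1 and 3, but wild type replicate 1 had the lowest mean log2 ratio of the 6 arrays (0.99). Both arrays had lower ratios than the other 4 for actin and for catalase (0.54 and 0.53 against 0.82 to 0.97). For Gapdh and ubiquitin wild type replicate 3 did not. The cause of this shared difference was not tested. A wrong label on wild type replicate 2 cannot be told apart from a true one. Of the 29 features with the smallest p without it, only 2 put it nearer the other wild type arrays. This restates the pattern, since 27 of the 29 belong to the set. The labelled groups are parted by 1 log2 unit on 67 features, such as srlf-34 (7.26 on this array against 10.24 to 10.35 in the mutant). At most 25 features do so when a mutant array takes the place of wild type replicate 2. At a gap of 1.5 log2 units the counts were 25 and at most 1. These counts rest on 1 array of 4, so they do not decide on the label. The genes of the set span 1.44 times the median of all genes in genomic length (permutation p = 1e-05, the smallest that 100000 draws can give, across genes). The draws were from all measured genes and were not matched on intensity, although a feature near the floor can hardly enter the set. Genomic length is also not transcript length. A loss of long transcripts thus stays open, and no biological explanation was tested.

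The third pattern was the distance of wild type replicate 3 from all other arrays, without which the ribosomal, histone and oxidative phosphorylation lists did not pass. An intensity-dependent distortion is not the whole of it, because removal of the trend over intensity took 22.7% of the variance of its deviations and left an SD of 0.58, against at most 0.43 on the other arrays. Degraded RNA is argued against by its 3'/5' ratios, which were the highest of the 6 arrays for 1 of 4 control genes, ubiquitin. How that array was scanned or summarised was not tested, and no biological explanation was tested.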
